A study of Homo sapiens with 6 samples.

How the data were processed

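Gene expression was measured in MDA-MB-231, an established human breast cancer cell line, on 6 Affymetrix U133 Plus 2.0 arrays, each hybridised with biotin-labelled RNA of 1 sample. Per the labels' protocols, 250000 cells were seeded per well in FBS, moved to medium without serum, given patient serum to 10%, and harvested after 4 days. The labels place 3 arrays in a group given serum of sedentary patients, called control serum here, and 3 in a group given serum of patients exposed to aerobic training, called exercise serum. Replicates were numbered 1 to 3 within each group in the order of deposit, so a shared number pairs no arrays. No label says whether the arrays of a group used serum of separate patients or separate wells of the same serum. The p-values therefore measure the spread between these arrays, which may be partly technical. Serum taken before training was not analysed here.

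The values used were the authors' deposited log2 values, 1 per probe set and array. Per the submitters' processing notes, the authors used RMA and the affy package, version 1.36.1. RMA subtracts background, gives all arrays 1 distribution of probe intensities, and summarises the probes of a probe set. The log base was taken from the values, which ran from 2.31 to 14.2 with array medians from 4.97 to 5.02. Stored values between 8 and 16 lay on steps of 0.002, in 100 percent of cases within a tolerance of 1e-04. That step is far below most differences reported. The smallest ones, such as 0.003 for MYC, are near it, and so their signs carry little weight. The genome build was not given in the sources used here, and no coordinates are given. Arrays give no read depth, and their number limits the precision.

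Of 54675 probe sets, 62 were controls of the array maker. Of the other 54613, the platform's annotation table gave 41091 exactly 1 gene symbol, 1801 several and 11721 none. Only those with 1 symbol were used. Their gene numbers matched the RefSeq table of assembly GRCh38.p14, used for names only, for 41037 probe sets, and 54 kept the platform's symbol. Probe sets of genes of X inactivation and the Y chromosome, 59 in all, were left out. Each of the 19740 remaining genes was represented by its probe set with the highest mean over the 6 arrays, and probe sets of a gene can disagree. A gene was tested where that mean reached 4.41, the 40th percentile of all non-control probe sets, which kept 14806 genes and left out 4934.

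Differences are exercise minus control serum on the log2 scale. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other tested genes, with adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list's members move on balance 1 way, were alternatives. Of 35 lists, 34 had at least 5 tested members; the list of fibroblast markers did not. The lists hold 613 distinct genes, of which 556 had a usable probe set and 509 were tested. The spread between arrays was compared by the root mean square difference over the tested genes. Single values per array were compared by exact permutation tests, 2-sided. With 3 arrays against 3 there are 10 splits, so no such p can be below 0.1.

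The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named the 10 genes highest and the 10 lowest among those past the threshold, filled up with the smallest p among genes with a difference of at least 0.3 and no overlap of the groups. It also named up to 4 members with the smallest p from each list described, and 10 fixed genes, of which 7 were tested; the other 3 had no usable probe set and were not analysed here. Genes named outside this rule are said to have been chosen after their values were seen. Alternatives were array medians subtracted, quantile normalization of the deposited values, cyclic loess, no level filter or one at the 60th percentile, the mean of a gene's probe sets, no probe sets ending in _x_at, array weights, eBayes with trend and robust, every probe set tested, thresholds of 0.1 and 0.2, a minimum of 1.5-fold, and leaving out each array in turn.

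The procedure was tested on simulated data with the real genes' levels. Their spread was taken from limma's moderated variances, which pull each gene's variance toward a common value. Genes of wide spread were thus simulated with less spread than they had, and the percentages called may differ from those in real data. Over 14806 genes and 20 simulations, limma called 68.1 percent of genes shifted by 0.3, 99.1 percent of those shifted by 0.5 and 100 percent of those shifted by 1 on the log2 scale, and 6.3 percent of its calls were unchanged genes. Camera called a list of 26 genes shifted by 0.1 in 100 percent of simulations, and 0.05 unshifted lists per simulation. Each simulation shifted many genes at once, which eases the Benjamini-Hochberg threshold for each of them. The percentages of genes called therefore do not apply to data in which few genes change. The simulated genes were independent, which real genes of a list are not. Figures were drawn with matplotlib 3.10.9.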

Results

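The series asks whether serum of breast cancer patients who had aerobic training alters gene expression in breast cancer cells, relative to serum of sedentary patients. The cells were MDA-MB-231, an invasive mesenchymal-type breast cancer line without estrogen receptor, grown for 4 days in 10% patient serum. The data are log2 RMA values of 54613 probe sets other than controls on 3 control-serum and 3 exercise-serum arrays. The arrays were alike: Pearson's r between pairs, taken across probe sets, which are not independent replicates, ran from 0.9977 to 0.9984 over all non-control probe sets, and the median value of an array from 4.97 to 5.02.

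No single gene separated the groups beyond the test's threshold, and differences were small. The only gene that differed by 1.5-fold or more was HMOX1, the heme-degrading enzyme heme oxygenase, at 1.65-fold, and its arrays overlapped. Of 14806 genes tested with limma, 0 passed an adjusted p of 0.05 and the smallest adjusted p was 0.344. The same test gave 1876 genes with an unadjusted p under 0.05, where 740.3 would be expected from uniform p-values; 652 of them were higher and 1224 lower in exercise serum. Thus 65.2 percent were lower, against 84.0 percent with array medians subtracted, 52.8 percent after quantile normalization and 49.3 percent after cyclic loess. The groups did not overlap in 2879 genes, or 19.4 percent, where chance gives 10 percent. Array weights raised the count under 0.05 to 3770. It was 988 without control-serum replicate 1, 1031 without exercise-serum replicate 1, 1079 without exercise-serum replicate 3 and 2813 without exercise-serum replicate 2.

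The genes that came first by the fixed rule are given with their values although none passed. The first of the higher ones was OXT, which encodes the hormone oxytocin, with 5.99 ± 0.06 (SD, n = 3) in control serum and 6.44 ± 0.12 (SD, n = 3) in exercise serum, a log2 difference of 0.45 ± 0.07 (SE). PLEKHG6 differed by 0.37 ± 0.06, HSF4, a heat shock transcription factor, by 0.35 ± 0.06, and DUSP8, a phosphatase of MAP kinases, by 0.35 ± 0.06 (SE). The amiloride-sensitive sodium channel subunit gene SCNN1D differed by 0.34 ± 0.06, the gel-forming mucin gene MUC5AC by 0.34 ± 0.07, and ZFP92, a zinc finger gene, by 0.31 ± 0.05 (SE). The other 3 were CATSPERZ, a sperm calcium channel subunit gene, at 0.34, and the noncoding DSCR9 and EXOC3-AS1, at 0.34 and 0.37. Their means over the 6 arrays ran from 4.64 for ZFP92 to 7.47 for DUSP8. The probe sets of OXT and DUSP8 are of a kind that can share probes with related genes.

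The first of the lower ones was PARD6B, a cell polarity gene, with 9.56 ± 0.12 (SD, n = 3) in control serum and 9.11 ± 0.03 (SD, n = 3) in exercise serum, a log2 difference of -0.45 ± 0.07 (SE). It was the 1 gene that limma with trend and robust called, at an adjusted p of 0.0316, against 0.344 in the default fit; over all settings the smallest adjusted p ran from 0.0316 to 0.713. RGS7, a regulator of G protein signalling, differed by -0.50 ± 0.11, SORBS2, an adaptor of the actin cytoskeleton, by -0.47 ± 0.13, and EDN1, the endothelin 1 precursor, by -0.35 ± 0.09 (SE). PKP2, a desmosome component, differed by -0.35 ± 0.08, SLAIN1, a microtubule plus-end gene, by -0.38 ± 0.07, and SSBP2, a single-stranded DNA binding protein gene, by -0.34 ± 0.07 (SE). The remaining ones were RP2 at -0.32, PTGR2 at -0.34 and CCDST at -0.31. With the mean of a gene's probe sets in place of the brightest, PARD6B was at -0.18, PKP2 at -0.18, RP2 at -0.11, EDN1 at -0.10, CCDST at -0.08, MUC5AC at 0.11 and DUSP8 at 0.24. DUSP8 was at 0.13 without probe sets ending in _x_at.

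**Figure D1:**
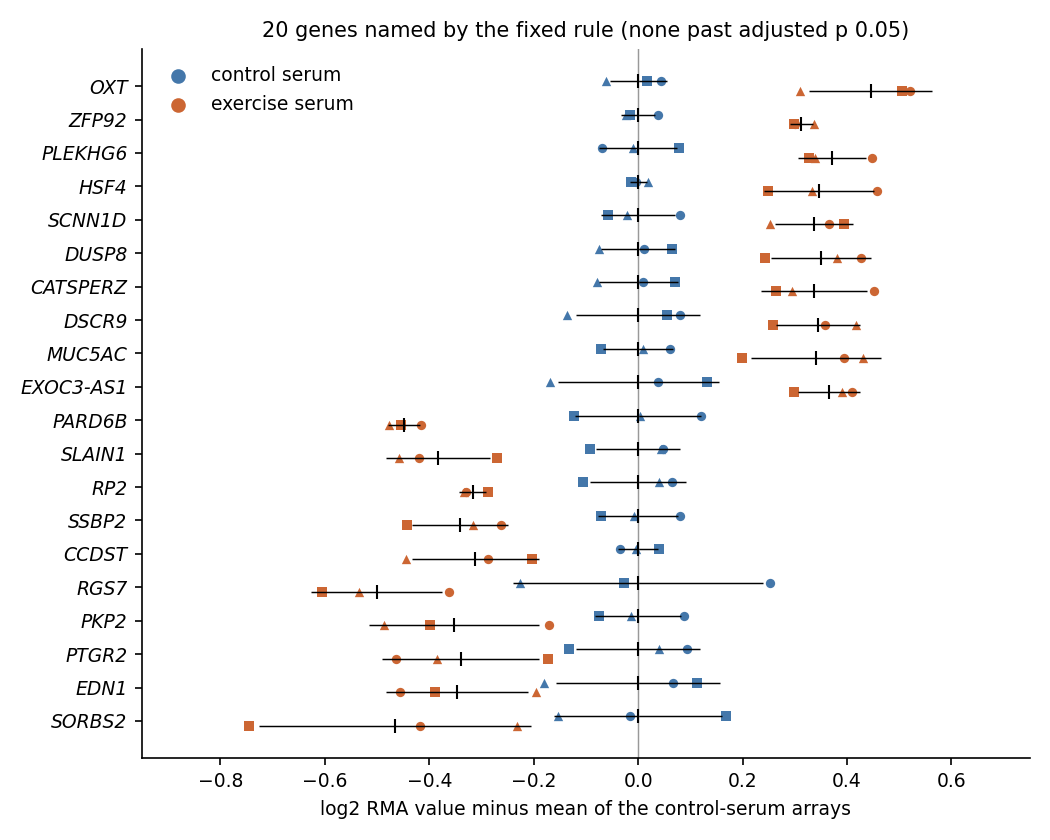
Log2 RMA values of the 20 genes named by the fixed rule, each minus the mean of the 3 control-serum arrays (x axis), for control serum (blue) and exercise serum (orange). Circles, squares and triangles are replicates 1, 2 and 3, and black bars are the mean ± SD of 3 arrays; the groups do not overlap in any of these genes by the rule's construction, and none passed an adjusted p of 0.05 in limma.

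Genes of cell division were slightly lower in exercise serum as lists. In the list of G2 and mitosis, 25 of 26 members were lower, with a p under 0.05 for 8 lower members and 1 higher, and with a median difference of -0.11. KIF23, a kinesin of the dividing cell's midbody, differed by -0.23 ± 0.07, HMMR, a hyaluronan receptor that acts on the spindle, by -0.19 ± 0.06, the cyclin genes CCNA2 and CCNB1 by -0.16 ± 0.06 and -0.14 ± 0.05 (SE). The exception was TOP2A, DNA topoisomerase II alpha, at 0.16 ± 0.07, named after its values were seen. In the list of S phase and DNA replication, all 26 members were lower and 4 had a p under 0.05, with a median of -0.08. The 4 were the cyclin E gene CCNE2 at -0.14 ± 0.06, the replication genes GINS2 at -0.12 ± 0.05 and MCM10 at -0.14 ± 0.06, and UHRF1, which maintains DNA methylation, at -0.13 ± 0.06 (SE). CCNE2 was at 0.06 with the mean of its probe sets.

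Camera called both lists, with adjusted p of 0.00162 for G2 and mitosis and 0.0046 for S phase. It called neither when the correlation was estimated: both had an adjusted p = 0.91 with an estimated correlation. That value was the smallest of any list there and was shared by most lists. The unadjusted p of that test was 0.198 for G2 and mitosis and 0.12 for S phase. Adjusted over the list alone, 0 members of either list passed, and 0 passed over all genes tested. The calls also ended after quantile normalization, where camera's adjusted p was 0.123 and 0.363, and after cyclic loess, at 0.0522 and 0.295. The medians stayed below 0 under every scaling, at -0.05 and -0.03 after quantile normalization and -0.05 and -0.02 after cyclic loess. In the same arrays, genes with a level of 8 or more were lower in exercise serum in 83.9 percent of cases, and the median level of both lists was 10.2. The 5' minus 3' signal of beta-actin was higher by 0.30 in exercise serum, and that of the dap and thr spike-ins by 0.53 and 0.42, without overlap of the groups. For GAPDH and the phe and lys spike-ins the difference was 0.06, 0.08 and 0.01. The exact permutation p of the beta-actin, dap and thr differences was 0.1, or 0.333 after Benjamini-Hochberg adjustment over 10 transcripts.

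Nuclear genes of oxidative phosphorylation were lower in exercise serum in 20 of 22 members, with a median of -0.08, and 2 had a p under 0.05. The complex I subunit genes NDUFV2 and NDUFB8 differed by -0.13 ± 0.05 each, COX7A2, a subunit gene of cytochrome c oxidase, by -0.11 ± 0.05, and NDUFA1 by -0.10 ± 0.05 (SE). NDUFB8 was at -0.02 with the mean of its probe sets. The other members, SDHC at 0.01 and ATP5F1A at 0, were named after their values were seen. Camera called the list, at an adjusted p of 0.0179, which became an adjusted p = 0.91 with an estimated correlation (unadjusted p 0.135). Adjusted over the list alone, 0 members passed. The call ended after quantile normalization (median -0.02, adjusted p 0.515 in camera) and cyclic loess (median -0.02, 0.59). It also ended with the stricter level filter, where the median stayed at -0.08 (0.0521), and without control-serum replicate 2 or exercise-serum replicate 3, where the median was -0.06 in both cases (0.111 and 0.106). This list's median level was 11.3, among the levels at which most genes were lower. The groups also differed in the 5' minus 3' signal of beta-actin, by 0.30, and in that of GAPDH by 0.06.

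Targets of NRF2, the transcription factor of the oxidative stress response, were higher in exercise serum in 16 of 21 members, with a median of 0.10, but the arrays of each group differed widely. HMOX1 was at 8.12 ± 0.76 (SD, n = 3) in control serum and 8.84 ± 0.86 (SD, n = 3) in exercise serum, a log2 difference of 0.72 ± 0.44 (SE). AKR1C1, an aldo-keto reductase, differed by 0.26 ± 0.06 and was the 1 member that passed adjusted over the list alone; 0 passed over all genes tested. Its near-identical relative AKR1C2 differed by 0.14 ± 0.08, and both probe sets can share probes; without such probe sets AKR1C1 was at 0.07. SOD2, mitochondrial superoxide dismutase, was at -0.14 ± 0.06 (SE). The other 4 members below 0, named after their values were seen, were TXN and GPX1 at -0.07, SOD1 at -0.06 and CAT at -0.02, genes of thioredoxin, glutathione peroxidase, cytosolic superoxide dismutase and catalase. Camera called the list, at an adjusted p of 0.00865, which became an adjusted p = 0.91 with an estimated correlation (unadjusted p 0.306). The call ended without control-serum replicate 1 (median 0.065, adjusted p 0.115 in camera), control-serum replicate 2 (median 0.05, 0.17) or exercise-serum replicate 2 (median 0.08, 0.165), and the median was 0.17 without control-serum replicate 3. HMOX1 was at 0.24 without exercise-serum replicate 2 and 1.16 without control-serum replicate 3. The list's call also ended with no level filter (median 0.095, adjusted p 0.0539 in camera) and without probe sets ending in _x_at (median 0.087, 0.0553). The median level of this list was 10.5, at which most other genes were lower, and its median lay at percentile 100 of random lists matched on level. Those random lists hold unrelated genes, while camera's estimated correlation between the NRF2 list's members was 0.445.

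**Figure D2:**
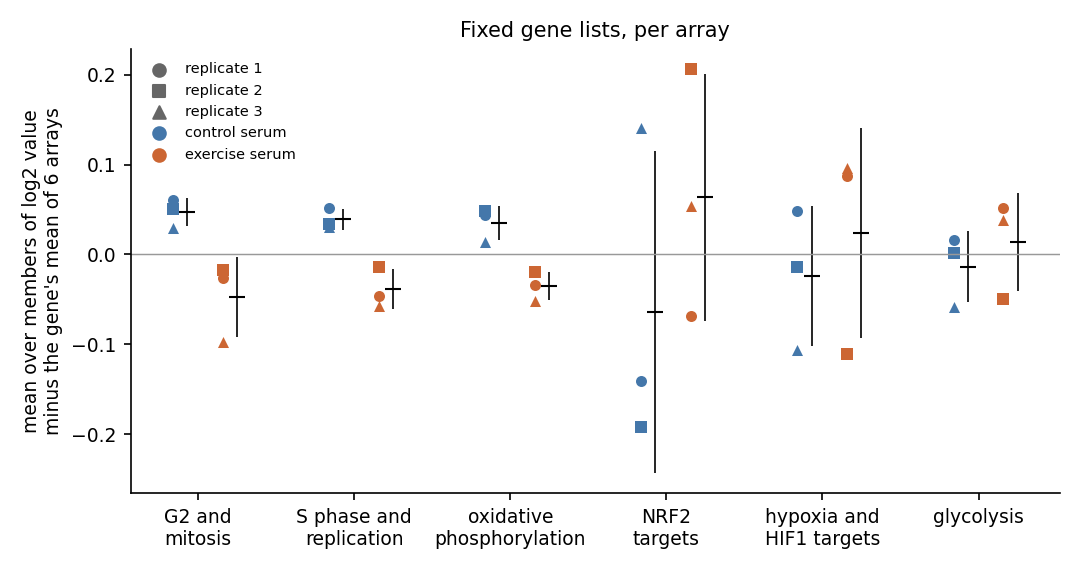
Mean over the tested members of each of 6 fixed gene lists of the log2 value minus the gene's mean of 6 arrays (y axis), for each array of control serum (blue) and exercise serum (orange); circles, squares and triangles are replicates 1, 2 and 3, and black bars the mean ± SD of 3 arrays. Control serum lay above exercise serum in all arrays for the lists of G2 and mitosis, S phase and oxidative phosphorylation, while NRF2 targets ran from -0.19 to 0.14 in control serum and from -0.07 to 0.21 in exercise serum.

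**Figure D3:**
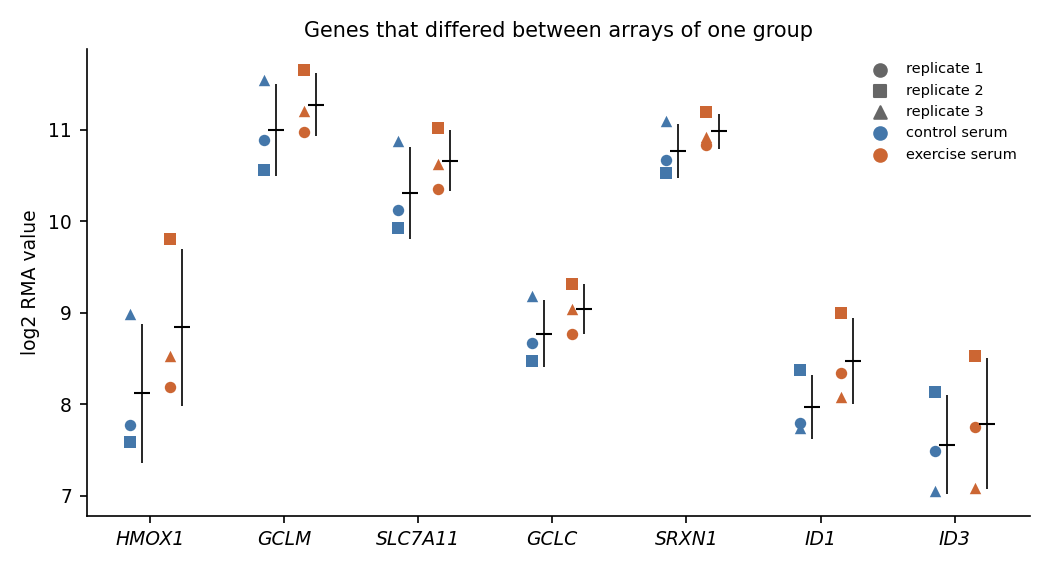
Log2 RMA values (y axis) of 5 NRF2 targets and of ID1 and ID3, all but HMOX1 named after their values were seen, for each array of control serum (blue) and exercise serum (orange); circles, squares and triangles are replicates 1, 2 and 3, and black bars the mean ± SD of 3 arrays. HMOX1 ran from 7.59 to 9.81, with the highest values in exercise-serum replicate 2 and control-serum replicate 3.

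The other 30 lists tested were not called by camera in the default fit. Targets of YAP and TEAD, which answer to cell tension and serum lipids, were lower in 16 of 16 members, with LATS2 at -0.11 ± 0.05, AJUBA at -0.11 ± 0.06, AMOTL2 at -0.10 ± 0.05 and CRIM1 at -0.13 ± 0.07 (SE), at a camera adjusted p of 0.1. It was called with no level filter (adjusted p 0.0462), the mean of probe sets (0.0208), array weights (0.0435) and trend and robust (0.0278). Its median level was 10.2, at which most genes were lower, and its median of -0.07 lay at percentile 16.6 of random lists matched on level. The 5' minus 3' signal of beta-actin was higher by 0.30 in exercise serum, and that of GAPDH by 0.06. Glucocorticoid targets were higher in 9 of 11 members (camera adjusted p 0.1), with ANGPTL4, an inhibitor of lipoprotein lipase, at 0.21 ± 0.15 and TSC22D3, the glucocorticoid-induced leucine zipper gene, at 0.20 ± 0.15 (SE). The list was called after cyclic loess (adjusted p 0.0262 in camera), with the stricter filter (0.0143), the mean of probe sets (0.0198), array weights (0.0161), trend and robust (0.0287), without control-serum replicate 3 (0.0384) and without exercise-serum replicate 2 (0.0135). Its median fell from 0.07 to 0.002 without exercise-serum replicate 3 (0.637) and to 0.017 without control-serum replicate 1 (0.413). Hypoxia targets were higher in 14 of 20 (0.1), with the oxygen-sensing hydroxylase genes EGLN3 at 0.37 ± 0.14 and EGLN1 at -0.12 ± 0.05 (SE). Glycolysis genes were higher in 13 of 19 (0.110), with the aldolase gene ALDOC at 0.18 ± 0.07 and GAPDH at 0.08 ± 0.05 (SE). Both had medians of 0.02, which turned to -0.004 for hypoxia and -0.006 for glycolysis with array medians subtracted. After quantile normalization and cyclic loess the medians were 0.08 and 0.08 for hypoxia and 0.047 and 0.075 for glycolysis, and both lists were called, at camera adjusted p of 0.00475 and 0.00619 for hypoxia and 0.0094 and 0.000958 for glycolysis. The hypoxia median was -0.02 without control-serum replicate 3 and -0.009 without exercise-serum replicate 3. Camera called that list without control-serum replicate 1 (adjusted p 0.0156) and without exercise-serum replicate 2 (0.00148), with the mean of probe sets (0.0208) and with trend and robust (0.0415). Against random lists matched on level, the medians of the glucocorticoid, hypoxia and glycolysis lists lay at percentile 100. The random lists hold unrelated genes, while camera's estimated correlation between members was 0.281, 0.417 and 0.389 in these lists. Glycolysis was called without exercise-serum replicate 2 (median 0.055, adjusted p 0.0158 in camera), with the stricter filter (0.0143) and with trend and robust (0.0312). Its median fell to 0.005 without control-serum replicate 3 (0.448), 0.006 without exercise-serum replicate 3 (0.445) and 0.008 without exercise-serum replicate 1 (0.495). Each of the lists of YAP, glucocorticoid, hypoxia and glycolysis genes had an adjusted p = 0.91 with an estimated correlation in camera. The unadjusted p of that test was 0.1495, 0.273, 0.454 and 0.449 in the same order.

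Genes of insulin and IGF signalling were lower in 12 of 20 members. IGFBP1, an insulin-repressed binding protein of IGF, differed by -0.26 ± 0.07, and IRS1, the insulin receptor substrate, by -0.20 ± 0.05 (SE). IGFBP1 and IRS1 passed adjusted over the list alone and 0 passed over all genes tested; camera's adjusted p for the list was 0.828. IGF1R, the IGF1 receptor, differed by -0.19 ± 0.07 and IGFBP6 by 0.14 ± 0.06 (SE). With the mean of their probe sets, IGFBP1 was at -0.14, IGF1R at 0.03 and IRS1 at -0.15. In cholesterol synthesis, 12 of 16 members were lower (camera adjusted p 0.393). HSD17B7, an enzyme of the pathway, differed by -0.20 ± 0.05 and was the 1 member that passed adjusted over the list alone, while INSIG1, a sterol-regulated brake on the pathway, was at -0.27 ± 0.10 (SE). The HSD17B7 probe set can share probes with related genes. NF-kB and cytokine genes were higher in 9 and lower in 9 of 18 members (0.504). The chemokine gene CCL5 differed by 0.21 ± 0.05, TNF by 0.23 ± 0.08 and TNFAIP2 by -0.22 ± 0.09 (SE). CCL5 was at 0.03 with the mean of its probe sets. TNF had a mean of 4.47 over all arrays, just above the level filter of 4.41, so its difference carries little weight. Genes of mesenchymal state and invasion were lower in 11 of 19 (0.956), with the collagenase gene MMP1 at -0.22 ± 0.08 and MMP9, a gelatinase gene, at 0.10 ± 0.05 (SE). The median levels of the insulin, cholesterol and mesenchymal lists were 8.46, 8.06 and 9.56, at which most genes were lower.

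Of the fixed genes, none passed. The proliferation marker MKI67 differed by -0.05 ± 0.06, the cyclin D1 gene CCND1 by -0.12 ± 0.06, MYC by 0.003 ± 0.064, VEGFA, an angiogenic factor, by -0.09 ± 0.09, and PDK4, a kinase that blocks pyruvate oxidation, by -0.14 ± 0.13 (SE). The cytokine gene IL6 was at -0.06 ± 0.10 (SE), and at 0.04 without exercise-serum replicate 2, where VEGFA was at 0.003. Scaling turned the sign of MYC, at -0.02 with array medians subtracted, and of MKI67, at 0.01 after quantile normalization. The mean of the probe sets turned CCND1 to 0.05 and VEGFA to 0.03.

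Of the red cell and platelet list, 6 of 8 tested members were higher in exercise serum (camera adjusted p 0.1), with the platelet glycoprotein gene GP9 at 0.25 ± 0.08, ALAS2 of heme synthesis at 0.19 ± 0.09, the hemoglobin gene HBB at 0.11 ± 0.08 and PPBP at -0.07 ± 0.06 (SE). HBB had 6.60 ± 0.07 (SD, n = 3) in control serum and 6.71 ± 0.15 (SD, n = 3) in exercise serum, and was at -0.05 without probe sets ending in _x_at, where the list's median turned from 0.07 to -0.007. The list was called with array weights (adjusted p 0.0356 in camera), trend and robust (0.0491) and without control-serum replicate 3 (median 0.134, 0.0134). Its median fell to 0.017 without control-serum replicate 1 (0.336), 0.038 without control-serum replicate 2 (0.228) and 0.04 without exercise-serum replicate 1 (0.267). In the default fit the list had an adjusted p = 0.91 with an estimated correlation in camera (unadjusted p 0.1205). Of the white blood cell list, 5 of 6 were higher (0.145), with the T cell receptor complex genes CD3E at 0.12 ± 0.05 and CD3D at 0.05 ± 0.07, and the B cell genes MS4A1 at 0.08 ± 0.07 and CD79A at 0.04 ± 0.08 (SE). Both lists had a median level of 5.6, at which most genes were higher in exercise serum. For luminal epithelium, 9 of 12 members were lower (0.768), at a median level of 8.79.

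Among the lists not yet named, camera's adjusted p was 0.19 for metallothioneins and interferon response, 0.41 for the BCL2 family, 0.717 for p53 targets, and 0.738 for MYC targets and for retinoid, vitamin D and aryl hydrocarbon receptor targets. It was 0.768 for iron, TGF-beta, ribosomal proteins, STAT3, PPAR, heat shock, angiogenesis and immediate early genes, 0.81 for sterol efflux, 0.881 for fatty acid synthesis, 0.915 for the unfolded protein response, 0.952 for autophagy and 0.956 for metastasis genes. Adjusted over the list alone, 0 of their members passed. Metallothioneins were called after cyclic loess (adjusted p 0.0226 in camera), with array weights (0.0445), with trend and robust (0.0415) and without control-serum replicate 3 (median 0.088, 0.0275). In the default fit they had a median of 0.044 and an adjusted p = 0.91 with an estimated correlation (unadjusted p 0.431). Without control-serum replicate 1 the median was 0.026 (0.549), and without control-serum replicate 2 it was 0.033 (0.626). Without exercise-serum replicate 1 or 3 it was 0.032 (0.444 and 0.637). Their median lay at percentile 99.97 of random lists matched on level, which hold unrelated genes. Camera's estimated correlation between the metallothionein list's members was 0.542. The probe sets of its members MT1E, MT2A and MT1G can share probes with related genes, which may add to that correlation. Without probe sets ending in _x_at the list had too few members to be tested. In 8 lists, none of them called in the default fit, the median, the mean and the direction in camera differed in sign.

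Differences depended on how bright a gene was. The 6214 genes with a level of 8 or more had a median difference of -0.06 and were lower in exercise serum in 83.9 percent of cases, while the 4356 genes with a level under 6 had a median of 0.03 and were higher in 63.6 percent. The median of the bright genes minus that of the dim ones, each gene taken relative to its mean of 6 arrays, was 0.05 ± 0.02 (SD, n = 3) in control serum and -0.05 ± 0.05 (SD, n = 3) in exercise serum, without overlap. The exact permutation p was 0.1, the smallest that 10 splits allow. Exercise-serum replicate 2 had a value of 0.01, nearer the control arrays than the other exercise arrays were. Over all tested genes the median difference was -0.03, and the median SD within groups was 0.08.

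**Figure D4:**
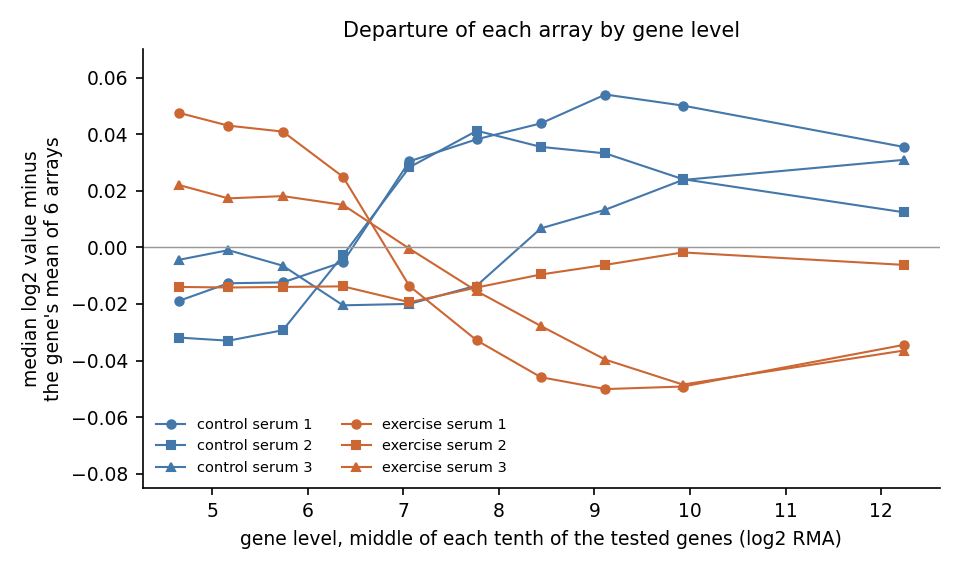
Median, over each of 10 level bins of equal size, of the tested genes' log2 value minus the gene's mean of 6 arrays (y axis), against the level in the middle of the bin (x axis, log2 RMA), 1 line per array, blue for control and orange for exercise serum. Among the 1480 genes at levels from 9.46 to 10.39 the control-serum arrays lie at 0.05, 0.02 and 0.02 and the exercise-serum arrays at -0.05, -0.002 and -0.05.

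Arrays of different groups were slightly farther apart on average than arrays of the same group, but not in every pair. The mean root mean square difference was 0.15 on the log2 scale between groups and 0.13 within them, a ratio of 1.11, with an exact permutation p of 0.1, the smallest possible. Exercise-serum replicate 2 was nearer to each control-serum array, at 0.137, 0.1339 and 0.1292, than to the other exercise-serum arrays, at 0.1392 and 0.1402. Control-serum replicates 2 and 3 were 0.1523 apart. The first principal component held 34.8 percent of the variance and the second 23.4 percent. On the first, exercise-serum replicate 2 lay at -1.07, exercise-serum replicates 1 and 3 at 8.93 and 8.81, and the control-serum arrays from -7.19 to -3.61. Signal at the 5' end relative to the 3' end, a sign of RNA integrity and of how far labelling reached, was higher with exercise serum for beta-actin, at -1.07 ± 0.15 (SD, n = 3) in control and -0.77 ± 0.10 (SD, n = 3) in exercise serum, a log2 difference of 0.30. For GAPDH the difference was 0.06. The exact permutation p was 0.1 for beta-actin and 0.2 for GAPDH, and after Benjamini-Hochberg adjustment over 10 transcripts 0.333 and 0.5.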

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

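Of the tests in this part, those on hybridisation controls and spike-ins, the NRF2 list's splits and spread, and the splits for both counts of genes were chosen only after the result was seen. The level-matched random lists were added after the lists' calls were seen, with their outcome for the cell cycle and oxidative phosphorylation lists not yet known.

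Control probe sets outside the comparison of genes gave a signal that differed between the groups. The 5' minus 3' signal was higher in every exercise-serum array than in every control-serum array for beta-actin, by 0.297 on the log2 scale, and for the poly-A spike-ins dap, by 0.527, and thr, by 0.42. The exact permutation p was 0.1 for each, the smallest possible, and 0.333 after Benjamini-Hochberg adjustment over 10 transcripts. The dap value was -2.87 ± 0.56 (SD, n = 3) in control serum, with control-serum replicate 2 lowest at -3.52, and -2.34 ± 0.07 (SD, n = 3) in exercise serum. The thr value was -2.62 ± 0.26 (SD, n = 3) in control serum and -2.20 ± 0.20 (SD, n = 3) in exercise serum. The other spike-ins, phe and lys, differed by 0.08 and 0.01.

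Bright genes were lower and dim genes higher in the exercise-serum arrays, with a median difference of -0.06 at levels of 8 or more. Compression of the signal at hybridisation or scanning that remained after RMA would lower the hybridisation controls as well. Their 9 probe sets differed by 0.07 ± 0.05 (SE), above the median of the bright genes by 2.7 standard errors. That goes against such compression only weakly, since the standard error is that of the controls alone, from 3 arrays per group. RMA gives all arrays 1 distribution, so compression that acted on all probes alike cannot be judged from these values. Amplification and labelling that reached the 5' ends less well in the control-serum arrays may account for the trend and cannot be told apart from the serum, since the spike-in signal and the group go together. Over the 6 arrays, the mean 5' minus 3' signal of dap and thr and the bright minus dim value had Spearman's rho of -0.77 (exact permutation p 0.103) and Pearson's r of -0.68 (exact permutation p 0.119, 0.119 after Benjamini-Hochberg adjustment over 2 relations), and r was -0.78 without the 2 arrays farthest from the median. The 3' probe sets of the poly-A spike-ins dap, thr, phe and lys were also lower in exercise serum, at -0.092, -0.07, -0.023 and -0.161. Those of beta-actin and GAPDH were at 0.025 and 0.023. The 5' minus 3' signal of dap and thr rose by more than their 3' signal fell, so their 5' probe sets were higher. The spread of these levels was not computed, so they do not decide the cause. An effect of the serum on many genes stays open and was not tested.

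The lists of G2 and mitosis, S phase and oxidative phosphorylation were lower in exercise serum and hold bright genes. Against 10000 random lists matched on level, the G2 and mitosis median lay at percentile 0.09. The level trend alone thus seldom gave so low a median in lists of unrelated genes. Camera's estimated correlation between this list's members was 0.309, and random lists do not account for variation that members share. The percentile therefore does not separate a shift of the list from such variation added to the level trend. S phase lay at percentile 7.04 and oxidative phosphorylation at 5.45, within the central 95 percent, so the level trend may account for both. For G2 and mitosis, an effect of exercise serum on cell division and a difference in cell number or growth between wells stay open. Variation among arrays shared by its members, and the difference in labelling or RNA quality seen in the 5' minus 3' signal, stay open too. None of these was tested. Camera's call for G2 and mitosis ended after cyclic loess, where its median moved from -0.11 to -0.05, and with an estimated correlation.

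NRF2 targets were higher in exercise serum by 0.127 in the list mean, but 4 of the 10 splits of the arrays gave a difference as large, the highest other being 0.267, so variation among arrays of 1 group may account for the difference. That variation itself exceeded that of unrelated genes. The SD of the list mean within groups was 0.16, at percentile 100 of 10000 random lists matched on level and 9.85 times their median. This argues against random variation of unrelated genes of this level. Many other lists of related genes also lay high, so a high percentile is not particular to NRF2 targets. Hypoxia, NF-kB, PPAR and glucocorticoid targets were at percentile 100, glycolysis at 99.98, MYC targets at 99.42 and heat shock genes at 99.1. Others did not, such as oxidative phosphorylation at 47.05 and S phase at 40.45. An iron load that differs between the sera, from heme or otherwise, predicts lower TFRC, the transferrin receptor gene, where HMOX1 is higher. Over the 6 arrays Pearson's r between them was 0.98 (exact permutation p 0.00139, 0.00278 after Benjamini-Hochberg adjustment over 2 relations, 0.98 without the 2 arrays farthest from the median of HMOX1). Spearman's rho was 1 (exact permutation p 0.00278). These values argue against an iron load that lowers TFRC, though TFRC spanned only 1.08-fold. They do not test a heme load that leaves TFRC unchanged. Differences between sera, between wells or in handling stay open and were not tested.

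The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. By limma, the count of genes past an adjusted p of 0.05 was 0 in the real split and at most 0 in the others, so 10 of 10 splits gave a count as large, and the real split had 1876 genes at an unadjusted p under 0.05. That count was as large in 1 of the 10 splits, the real one, the highest other being 1438. Camera called 4 lists in the real split and at most 8 in another, and 6 of the 10 splits gave as many.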

How the results depend on the processing

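The alternatives chosen only after seeing the data were cyclic loess for the spread between arrays, leaving out arrays for that spread and for array quality, level-matched random lists, and recording the adjusted p in place of the median for lists that no setting called. No paired analysis was possible because the labels give no numbers shared between the groups. By limma 0 genes passed in every setting except trend and robust, where 1 did, PARD6B, at an adjusted p of 0.0316; the default fit had 1876 at an unadjusted p under 0.05. That count was 3770 with array weights and 988 to 2813 with 1 array left out, lowest without control-serum replicate 1 and highest without exercise-serum replicate 2. The 4 lists called became 7 with the mean of probe sets, 8 with array weights, 10 with trend and robust, 0 with an estimated correlation and 0 with fry, and 2 to 7 with 1 array left out, lowest without control-serum replicate 2 and highest without control-serum replicate 3. Fry's mixed test called 1 list. Both cell cycle lists were called with each array left out. Over all alternatives camera's and fry's adjusted p ran to 0.91 for each of the 4 lists, from 7.57e-05 for G2 and mitosis, 0.000261 for S phase, 0.000356 for oxidative phosphorylation and 6.94e-07 for NRF2 targets, the last without control-serum replicate 3.

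Of 82 genes named, 18 of 1203 values in other settings had the other sign. Signs turned as follows. With array medians subtracted, MYC was at -0.024 and the medians of hypoxia and glycolysis at -0.004 and -0.006. After quantile normalization IL6 was at 0 and MKI67 at 0.007, and after cyclic loess MKI67 was at 0.005 and ribosomal proteins at 0.038, where camera called them (adjusted p 0.0321; in the default fit adjusted p = 0.91 with an estimated correlation). With the mean of probe sets CCND1 was at 0.045, IGF1R at 0.027, VEGFA at 0.028, CCNE2 at 0.059, ZEB1 at 0.081 and ribosomal proteins at 0.003. Without probe sets ending in _x_at HBB was at -0.047 and the red cell and platelet list at -0.007, and with array weights MYC was at -0.018. With 1 array left out the ranges were -0.059 to 0.05 for MYC, -0.02 to 0.082 for CD79A, -0.006 to 0.116 for CD3D, -0.165 to 0.036 for IL6, -0.151 to 0.003 for VEGFA, -0.018 to 0.081 for hypoxia and -0.023 to 0.002 for ribosomal proteins. Of the changes above, the cause was not tested. Of 344 medians of the 23 lists called in no setting, 35, from 14 lists, had the other sign elsewhere. The median of all tested genes was -0.056 with array medians subtracted, -0.005 after quantile normalization and -0.002 after cyclic loess. The ratio of spread between to within groups was 1.06 to 1.19 in all settings, and the beta-actin difference 0.21 to 0.345 with 1 array left out. Genes near background were limited by signal, and 4934 below the filter were not tested by default.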

Other observations

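All tests in this part were chosen only after the result was seen, as were the genes outside the fixed rule.

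Some targets of NRF2 varied widely among arrays of the same group. The 20 genes with the highest SD within groups held 4 of the 21 tested members of that list: HMOX1, the subunit genes GCLM and GCLC of the enzyme that starts glutathione synthesis, and SLC7A11, the cystine transporter gene. HMOX1 spanned 4.66-fold over the 6 arrays, GCLM and SLC7A11 2.13-fold, GCLC 1.8-fold, and SRXN1, the sulfiredoxin gene, 1.58-fold; TRIM16, outside the fixed list, spanned 1.89-fold. These 6 genes, picked for their spread, were highest in exercise-serum replicate 2 and control-serum replicate 3. Of the list's other members, TXNRD1 and NQO1 were also highest in these arrays. TXNRD1 was at 12.803 in exercise-serum replicate 2 and 12.764 in control-serum replicate 3, and NQO1 at 11.152 and 11.168. Some members were not: FTL, the ferritin light chain gene, was highest in exercise-serum replicates 1 and 3, and SOD2 in control-serum replicates 3 and 1. AKR1C1 was highest in exercise-serum replicate 3, at 7.171, but close to that in exercise-serum replicate 2, at 7.163. Camera's estimated correlation between the list's members was 0.445.

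ID1 and ID3, inhibitors of differentiation that respond to BMP signalling, spanned 2.39-fold and 2.77-fold. Both were highest in exercise-serum replicate 2, at 8.99 and 8.52, with differences between the groups of 0.50 ± 0.23 and 0.23 ± 0.35 (SE) and limma adjusted p of 0.4 and 0.777. The noncoding MALAT1 spanned 2.7-fold with a difference of 0.03 ± 0.31 (SE). Among other lists, the SD of the list mean within groups was 5.02 times the median of level-matched random lists for hypoxia, 4.18 times for NF-kB, 3.85 times for PPAR and 3.77 times for glucocorticoid targets.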
